A study of Homo sapiens with 3 samples.

How the data were processed

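Total RNA of HSC-3 cells in 3 conditions (parental, scrambled shRNA, shRNA against DKK3) was measured on 3 arrays, 1 per condition. Per the labels' protocols, the RNA was amplified to amino allyl RNA, coupled to Cy5 and hybridised in a 1-colour design, the shRNA vectors were lentiviral, and both shRNA lines were grown with puromycin. Groups were taken from the sample titles and shRNA labels.

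The scanner files hold the deposited intensity values. Per the file headers, the authors' column used here is the median brightness of each spot at 635 nm, put together from scans at 3 gains by fitted lines. These values were not background subtracted, since 2680 blank spots had means of 50.1, 55.7 and 46.9 on the parental, shScr and shDKK3 arrays. The scanner software and the array design were not given in the sources used here. A second deposited column, named as the background median, followed the brightness of its own spot (r from 0.891 to 0.935 across spots) and was not used as a background in the main setting.

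The authors' deposited table of normalised intensity was set against the scanner values of the same arrays. Its columns lie on straight lines of the spot median with slopes of 1.41, 1.83 and 1.04. They equal the spot median minus the mean of the blank spots, after leaving out 5% at each end, divided by the slope. The median of each column is 25.0. The scale is linear, with no centring per gene and the same direction as the scanner values. This was worked out from the values, and the labels state no normalisation for it.

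The spot medians were corrected with the normexp method of limma 3.58.1 in R 4.3.3, fitted on all spots with an offset of 50, and then quantile normalised over the gene probes of the 3 arrays on the log2 scale. The offset shrinks the folds of dim genes, and nearly no gene of the lowest tertile of expression can reach 2-fold. A probe was detected where its spot exceeded the mean plus 2 SD of the blank spots, which gave limits of 54.3, 59.1 and 49.2. Detected probes numbered 19190, 19599 and 19887 of 24460. Copies of a positive control spot, 24 per array, had an SD of 0.10, 0.14 and 0.08 (log2) within the arrays, which measures spot noise alone. Probes marked as not good on any array, 9 in all, were left out.

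Gene names came from the platform annotation of the deposited table, which gave 1 symbol for 20236 probes, several for 0 and none for 4224. Of 17614 symbols, 14990 are current in the RefSeq table of assembly GRCh38.p14, 2538 are a single older synonym and 86 had no single match. Symbols are given as annotated, with the current one beside them where it differs for a named gene. Genomic lengths came from the same RefSeq table, which held one for 99.7% of the lower and 98.8% of the higher genes apart from both controls. A gene was represented by its probe with the highest mean, and 2506 genes had more than 1 probe. A gene entered a comparison where it was detected on the brighter array. XIST and Y-linked genes are neither named nor plotted.

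No test between conditions was possible with 1 array each, and no p-value was computed. Genes were counted where the log2 difference was at least 1 in size. Gene lists, 37 in number, were fixed before the data were examined, as were the comparisons, the rule for named genes and the first set of alternatives. The median of each list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Such a percentile describes these arrays only. The spread for a gene was the robust SD of the difference between the control arrays over the 500 genes nearest in expression. Overlaps of comparisons that share an array were set beside 100 simulations of unchanged arrays, in which genes varied independently.

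By the fixed rule, the text names DKK3, then the 12 higher and 12 lower genes with the largest smaller difference to both controls among genes detected on all 3 arrays and at least 2-fold different from each. It adds up to 4 members of each list that meet the same criterion, or up to 3 with the largest difference to shScr where none does, and the 6 higher and 6 lower genes for shScr against parental. Up to 4 genes each way that were detected on 1 side only are named with bounds. A bound sets the brighter side against the higher of the dim probe's own value and the lowest normalised signal among detected probes. Uncharacterised loci are counted but not named. Not all genes that the rule allows are described, and some are not reported here.

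The alternatives were plain subtraction of the blank mean, an offset of 16, no background correction, scaling to the median or the 75th percentile, cyclic loess, the authors' table on the log2 scale, no filter on dim probes, detection on all 3 arrays, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, and, for lists, the parental array or the mean of both controls as control. The background column as local background, and the removal of the trend with gene length by a running median, were added after the data were seen.

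The steps were tested on simulated arrays made from the parental values with the gains and spot noise of the real arrays, in which 200 genes of the shDKK3 array were changed. For that array against both controls, over 14031 genes compared, 2-fold calls found 2 of 22 genes changed 2-fold, 24 of 25 changed 3-fold and 19 of 20 changed 4-fold in the top tertile of expression. In the middle tertile they found 0 of 24, 2 of 24 and 11 of 26, and in the lowest tertile 0 of 21, 0 of 17 and 0 of 21. No unchanged gene was called, but these arrays carried spot noise alone, so nearly none could be. The real control arrays differed more, with a robust SD of 0.39 (log2) in the top tertile. The shares found and the lack of false calls therefore hold for spot noise alone. A list raised 1.5-fold came out at percentile 100 in both shDKK3 comparisons. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the remaining steps.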

Results

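Total RNA of HSC-3, a cell line from a human tongue squamous cell carcinoma, was measured on 1-colour microarrays in 3 conditions. Parental cells carried no vector, shScr cells carried a scrambled short hairpin RNA (shRNA), and shDKK3 cells carried a lentiviral shRNA against DKK3, a secreted glycoprotein of the dickkopf family. Each condition was measured on 1 array, so there were no replicates, and every difference given here is between these arrays and not between the conditions. Of 24460 gene probes, 19190 (78.5%) lay above the blank spots on the parental array, 19599 (80.1%) on the shScr array and 19887 (81.3%) on the shDKK3 array. The median probe stood 25.1 intensity units above the blanks on the parental array, 28.4 on the shScr array and 18.2 on the shDKK3 array. The number of arrays limits the precision of all values. The study title names the question as the effect of DKK3 knockdown on the malignant behaviour of these cells. The arrays allow comparisons of the shDKK3 array with each control array, and of the controls with each other.

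DKK3 itself, the gene targeted by the shRNA, had its lowest signal on the shDKK3 array. The authors' deposited values were 309 on the parental array, 226 on the shScr array and 170 on the shDKK3 array, on a scale where each array's median is 25. After normalisation DKK3 was 1.31-fold lower on the shDKK3 array than on the shScr array (log2 difference -0.39) and 1.64-fold lower than on the parental array (log2 difference -0.71). It was also 1.25-fold lower on the shScr array than on the parental array (log2 difference -0.32). The difference to shScr lay at percentile 17.1 of all compared genes and the difference to parental at percentile 6.69. Genes of like expression had a robust SD of 0.39 (log2) between the control arrays, so the DKK3 difference to shScr was about the size of that spread and did not reach 2-fold. That difference was -0.80 with scaling to the median. Without the trend with gene length, a setting added after the data were seen, it was -0.23, and the difference to parental was -0.49. With the second deposited column as local background, a setting added after the data were seen, DKK3 was 0.17 above shScr and 0.23 above parental. DKK3 was measured by 1 probe. DKK1, a secreted Wnt antagonist of the same family, differed more, at -1.34 against shScr and -1.30 against parental (log2), although in the authors' deposited values it was 1.77-fold lower than shScr. The list of DKK family genes and receptors had a median of 0.19 against shScr (percentile 91.5 among random lists). In it, 2 members were at least 2-fold higher, and DKK1 was the 1 lower. Against parental the list had a median of 0.10 (percentile 77.7), with 0 members at least 2-fold higher and 1 lower.

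Among the genes by which the shDKK3 array stood apart from both controls, several squamous keratinocyte genes had higher signal, and DEK, ANXA1, ITGB1 and CCND1 had lower signal. SPRR1B, a precursor of the cornified envelope, was 2.54 higher than shScr and 2.98 higher than parental on the log2 scale, and S100A8, a calcium-binding protein of stratifying and inflamed epithelium, was 2.26 and 2.27 higher. The stress- and differentiation-associated keratins KRT6B (2.12 and 2.10) and KRT16 (1.94 and 2.18), the basal keratin KRT15 (1.65 and 1.63) and the water and glycerol channel AQP3 (2.77 and 2.003) were higher in the same way. DEK, a chromatin-binding oncoprotein, was among the lowest relative to the controls, at -2.74 against shScr and -2.29 against parental. Also lower were ANXA1, a phospholipid-binding protein of the cornified envelope (-2.14 and -1.86), ITGB1, the integrin beta-1 subunit (-1.75 and -1.80), and CCND1, the G1 cyclin D1 (-1.79 and -1.67). In all, 84 genes were at least 2-fold higher and 306 at least 2-fold lower on the shDKK3 array than on each control.

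Among the other genes with the highest signal relative to both controls, ID3, an inhibitor of basic helix-loop-helix factors, was 1.51 above shScr and 1.66 above parental. SLPI, a secreted leukocyte protease inhibitor of epithelia, was 1.47 and 1.55 above them. LYL1, a basic helix-loop-helix factor of blood cells, was 1.42 and 1.60 above them, GAST, the gastrin precursor, 1.38 and 1.45, and HSPA2, a member of the HSP70 family, 1.89 and 1.38. KRT6C was 1.35 above shScr and 2.57 above parental, and it already differed by 1.21 between shScr and parental. KRT6A, KRT6B and KRT6C are near-identical paralogs, and their separate probe values are uncertain for that reason. In the authors' deposited values, which carry no added offset, SPRR1B was 25.2 on the parental array, 43.3 on the shScr array and 491 on the shDKK3 array. S100A8 was 6.08, 5 and 169 in the same order, and AQP3 was 173, 78.7 and 882. For the lower genes named first, the deposited values gave smaller folds against shScr than the normalised ones. DEK was 4.81-fold lower there (6.67-fold after normalisation), ANXA1 2.63-fold (4.41-fold), ITGB1 2.58-fold (3.37-fold) and CCND1 2.08-fold (3.47-fold).

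Among the genes with the lowest signal relative to both controls, INHBA, the subunit of activin A, was at -1.71 against shScr and -2.23 against parental. KRR1, a factor of small ribosomal subunit assembly, was at -2.01 and -1.72, and EPCAM, an epithelial adhesion molecule, at -1.72 and -1.66. The Golgi and secretory pathway genes ERGIC2 (-1.80 and -1.76) and GOLGA4 (-1.73 and -1.64) and the transmembrane gene TMEM123 (-1.66 and -1.67) had similar differences. The probe listed for HSP90AA2, now named HSP90AA2P, was at -2.55 and -1.81. That locus is now annotated as a pseudogene near-identical to HSP90AA1, so the identity of its signal is uncertain. The second probes of ANXA1 (-2.30 and -1.57), ERGIC2 (-2.52 and -2.06), GOLGA4 (-1.97 and -1.49) and TMEM123 (-1.58 and -1.09) lay on the same side as the probes given above.

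**Figure D1:**
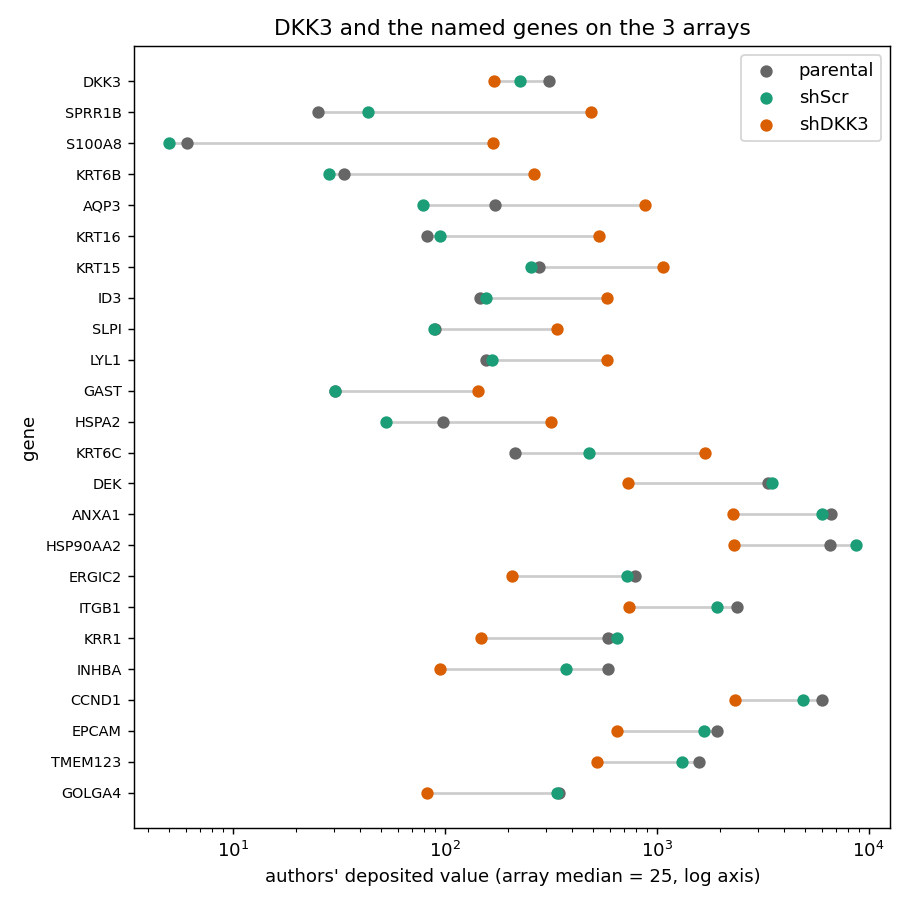
Deposited values of DKK3 and of genes with the largest differences to both controls (vertical axis), on a log axis scaled so that each array's median is 25; each point is 1 array and grey lines span the 3 arrays. DKK3 is lowest on the shDKK3 array (170, against 226 and 309), and the shDKK3 point lies outside both control points for each gene shown.

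Some genes were above the blanks on the shDKK3 array alone, or on both controls but not on the shDKK3 array, so their differences are bounds. IGFL1, an insulin growth factor-like gene, was at least 2.33-fold higher there than on both controls, SPP1, which encodes osteopontin, at least 1.42-fold and the zinc finger genes ZNF14 and ZNF462 at least 1.46-fold and 1.29-fold. Among genes not above the blanks on the shDKK3 array, XPNPEP3 was at least 1.44-fold lower, GULP1 at least 1.31-fold, and both SMCHD1 and SENP7 at least 1.24-fold.

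Both comparisons behind these counts share the shDKK3 array. In 100 simulations of unchanged arrays, 23.2 genes on average were 2-fold higher than both controls and 23.0 lower, with at most 34 and 36. These simulations gave each array the same spread, taken from the difference between the control arrays, with genes varying independently. Independent lists of the observed sizes would share 3.88 higher and 20.7 lower genes. The differences to the 2 controls correlated at r = 0.809 across genes, which are not independent replicates, against 0.502 in the simulation. Their covariance was 0.182 against 0.0490. Part of the excess may still come from the shared array, since the simulations leave out any larger variation of that array as a whole. By the same rule the shScr array stood apart from the other arrays in 34 higher and 72 lower genes, and the parental array in 32 higher and 6 lower genes. The 72 lower genes of the shScr array also exceeded the simulated highest of 36, so exceeding it is not particular to the shDKK3 array. Lower genes made up 78.5% of those apart from both controls, and this share was 92.1% with scaling to the median and 64.7% with scaling to the 75th percentile.

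**Figure D2:**
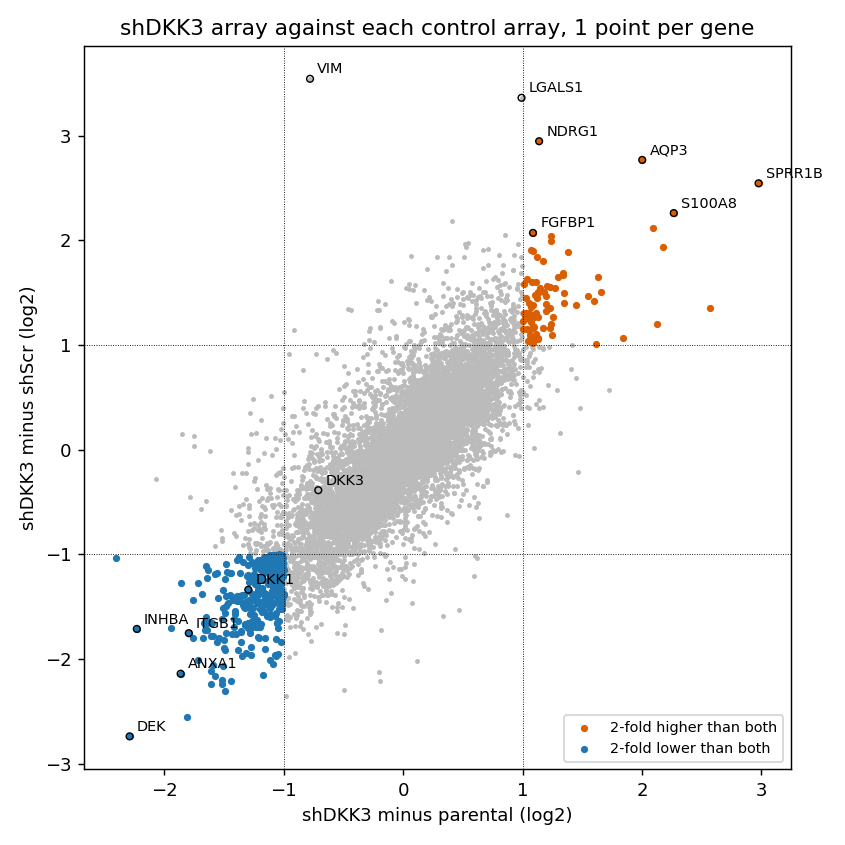
Log2 difference of the shDKK3 array to the parental array (horizontal) and to the shScr array (vertical), 1 point per gene compared with both except XIST and Y-linked genes, with dotted lines at 2-fold and genes 2-fold different from both controls in colour. SPRR1B and DEK lie at opposite ends, DKK3 lies inside the 2-fold lines, and VIM and LGALS1 lie far from shScr but not 2-fold from parental.

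The shDKK3 array was next set against shScr, the control that shares vector, virus and puromycin selection. Genes of hypoxia and glycolysis and of cholesterol biosynthesis, and genes of keratinocyte differentiation, had higher signal as groups, and heat shock genes had lower signal. The median of 29 hypoxia and glycolysis genes was 0.60 higher (percentile 100 among random lists of like expression), with 8 members at least 2-fold higher and 0 lower. NDRG1, a hypoxia- and differentiation-induced gene, was 2.95 higher and DDIT4, an inhibitor of mTORC1 signalling, 1.47 higher. The shScr array itself lay below parental for this list (-0.27, with 5 members at least 2-fold lower) and for NDRG1 (-1.81). Part of the hypoxia difference to shScr therefore lies between the control arrays. The median of 37 keratinocyte differentiation genes was 0.32 higher (percentile 100), with 4 members at least 2-fold higher and 1 lower, the latter being ANXA1. The 18 heat shock genes had a median of -0.76 (percentile 0), with 7 members at least 2-fold lower. Among them, the mitochondrial chaperonin HSPD1 was at -1.96, the HSP90 co-chaperone CHORDC1 at -1.83 and the HSP40 member DNAJA1 at -1.66.

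The 21 cholesterol biosynthesis genes had a median 0.46 above shScr (percentile 99.5), with 7 members at least 2-fold higher and 1 lower. MVK, mevalonate kinase, was 1.68 higher, DHCR7, which makes the last step to cholesterol, 1.499, FDPS, farnesyl diphosphate synthase, 1.40, and INSIG1, a regulator of sterol sensing, 1.31. The second INSIG1 probe gave 0.28. The 18 YAP/TAZ target genes had a median of -0.18 (percentile 1.87), inside the random range with the mean of probes. F3, the tissue factor gene, was at -1.40, CTGF, now named CCN2, at -1.19 and CRIM1 at -1.04. In the authors' deposited values F3 was 1.56-fold lower. The 32 other growth factors and receptors had a median of 0.16 (percentile 98.7), inside the random range under 6 of 10 alternatives. Against parental this list was at 0.06 (percentile 65.5), and the shScr array itself lay below parental for it (-0.18, percentile 0). FGFBP1, a carrier protein of fibroblast growth factors, was 2.07 above shScr and 1.09 above parental. The 27 matrix proteases and inhibitors had a median of -0.13 against shScr (percentile 1.31). It stayed outside the random range with the same sign under 1 of 10 alternatives. Its sign was opposite with scaling to the 75th percentile (0.28) and in the authors' deposited values (0.14). The median of all genes was higher still in these settings, at 0.36 and 0.32. SERPINB2, a plasminogen activator inhibitor, was at -1.41 and the membrane protease ADAM9 at -1.07.

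The 17 basal keratinocyte genes had a median of 0.30 (percentile 96.3), inside the central 95% of random lists, although 6 of them were at least 2-fold higher. This median lay above the random range under 6 of 10 alternatives, such as subtraction of the blank mean (0.70). Against parental the median was 0.10 (percentile 64.1), with 8 members at least 2-fold higher, all of them keratins, and 1 lower, DST (-1.30), named after its values were seen. Not all of these keratins are basal, since the list also holds KRT6B and KRT16, described above as stress- and differentiation-associated, with KRT6A and KRT6C. Against shScr, the 21 Wnt/beta-catenin target genes had a median of 0.05 (percentile 69.9) and the 33 Wnt ligands, receptors and antagonists 0.06 (percentile 83.1). The 24 PI3K-Akt-mTOR components had a median of 0.02 (percentile 39.4), and these lists all lay inside the random range. Single members of these lists differed in both directions. WNT10A was 1.55 higher and the receptor FZD6 was at -1.19, the kinase AKT2 was 1.45 higher and the S6 kinase RPS6KB1 was at -1.35. Against parental these genes missed 2-fold, at 0.96, -0.70, 0.55 and -0.61. Between the controls (shScr minus parental) they had the opposite sign, at -0.59, 0.49, -0.91 and 0.74. The 20 mesenchymal genes had a median of 0.07 against shScr (percentile 93.1). In that list VIM, the intermediate filament vimentin, was 3.54 higher and FN1, fibronectin, was at -1.11. Against parental VIM was at -0.78 and FN1 at -0.48, and between the controls they were at -4.32 and 0.63. Of 15148 genes compared, 448 were at least 2-fold higher and 679 at least 2-fold lower on the shDKK3 array than on the shScr array. The share of lower genes was 60.2% and moved to 84.9% with scaling to the median, 71.0% with cyclic loess and 42.2% in the authors' deposited values.

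Against the parental array, keratinocyte differentiation and cholesterol genes again had higher signal on the shDKK3 array, and mitotic, inflammatory, YAP/TAZ target and integrin genes had lower signal. Of these lower groups only the YAP/TAZ targets also lay below the random range against shScr. The differentiation list had a median 0.29 higher (percentile 100), with 6 members at least 2-fold higher and ANXA1 lower, and the cholesterol list a median 0.46 higher (percentile 99.9), with 5 members at least 2-fold higher. The hypoxia and glycolysis list was 0.23 higher (percentile 98.3), inside the random range under 3 of 10 alternatives, with the 2 members NDRG1 (1.14) and DDIT4 (1.19) at least 2-fold higher and 1 lower. The latter was PLOD2 (-1.13), named after its values were seen. The 19 replication-dependent histone genes were 0.29 higher (percentile 99.4), inside the random range under 3 of 10 alternatives, with HIST1H1A, a linker histone gene now named H1-1, 1.08 higher. The heat shock list, at -0.07 (percentile 16.7), lay inside the random range in this comparison.

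The 29 genes of G2/M and mitosis had a median of -0.64 against parental (percentile 0), with 9 members at least 2-fold lower and 0 higher. Against shScr the same list was at 0.20 (percentile 78.1), with 6 members at least 2-fold higher and 0 lower. The 28 G1/S and replication genes had a median of -0.27 (percentile 2), inside the random range under 6 of 10 alternatives, and PRIM1, the catalytic primase subunit, was at -1.16. The 35 NF-kB and inflammatory genes had a median of -0.26 (percentile 0), with 8 members at least 2-fold lower, and against shScr the list was at 0.14 (percentile 97.1), above the random range under 4 of 10 alternatives. Of its members, 4 were at least 2-fold lower and 1 higher than on the shScr array. IL8, the neutrophil chemokine now named CXCL8, was at -2.40 against parental (-1.03 against shScr). BIRC3, an inhibitor of apoptosis, was at -1.48 (-1.10 against shScr) and the cytokine IL1A at -1.44 (-1.18 against shScr). The YAP/TAZ target list had a median of -0.39 (percentile 0.01) with F3 at -1.37, CTGF at -1.25 and CRIM1 at -1.07. The 22 integrins and laminins had a median of -0.19 (percentile 0.20), with ITGB1 and the collagen-binding subunit ITGA2 (-1.498) at least 2-fold lower, and against shScr the list was at 0.08 (percentile 86.6). The matrix protease list was at -0.10 (percentile 0.78) with SERPINB2 at -1.55 and ADAM9 at -1.27. It stayed below the random range with the same sign under 7 of 10 alternatives. Its median was 0.10 with scaling to the 75th percentile, where that of all genes was 0.26.

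Other lists lay inside the random range against both controls in the main setting while holding members 2-fold different from each. Against shScr, the motility list lay above that range and the NRF2 and oxidative stress list below it under 6 of 10 alternatives each, at 0.50 and -0.49 after subtraction of the blank mean. In the main setting these lists were at -0.04 and 0.01 against parental. Between the controls (shScr minus parental) they were at -0.18 and 0.23, outside the random range. Against parental, the ribosomal protein list lay above it under 2, and the ERK pathway output list below it under 2 (-0.41 and -0.39). In the motility list, RDX, which links actin to the membrane, was at -1.15 against shScr and -1.08 against parental. In the interferon list, IFI6 (1.06 and 1.07) and UBE2L6 (1.31 and 1.03) were higher. BIRC2, an inhibitor of apoptosis, was at -1.80 and -1.55, the endoplasmic reticulum chaperone HSP90B1 at -1.02 and -1.37, and the thioredoxin reductase TXNRD1 at -1.15 and -1.63. The aldo-keto reductase AKR1B10 was 1.16 and 1.17 higher, but its second probe missed 2-fold, at 0.99 and 0.94. The ribosomal protein genes RPL7 (-1.23 and -1.23) and RPS24 (-1.29 and -1.22) were lower within a list whose medians were 0.05 and 0.07. In the authors' deposited values they missed 2-fold, with RPL7 1.35-fold and 1.65-fold lower and RPS24 1.34-fold and 1.61-fold lower, and HSP90B1 and TXNRD1 missed it there against shScr. Against parental, 129 of 14962 genes were at least 2-fold higher and 455 at least 2-fold lower. The share of lower genes was 77.9% and moved to 91.8% with scaling to the median and 65.9% with scaling to the 75th percentile.

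The control arrays also differed from each other, which sets a yardstick for the differences above. On the shScr array, heat shock and oxidative stress genes had higher signal than on the parental array, and vimentin, inflammatory, mitotic and hypoxia genes had lower signal. VIM was at -4.32, with deposited values of 5006 on the parental array, 212 on the shScr array and 3695 on the shDKK3 array. The galectin LGALS1 was at -2.37, the receptor kinase AXL at -2.06, and the acute-phase genes SAA1, PTX3 and SERPINA1 at -2.002, -1.89 and -1.88. HIST1H4H, now named H4C8 (2.14), the autophagy gene GABARAPL1 (1.99), the glutathione synthesis gene GCLM (1.92) and HIST2H2AA4, now named H2AC19 (1.80), were higher. The inducible HSP70 paralogs HSPA1A (2.01) and HSPA1B (1.93), whose probes may not be separable, were higher as well.

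As groups, the 18 heat shock genes had a median 0.45 higher on the shScr array than on the parental array (percentile 100) and the 22 NRF2 and oxidative stress genes one 0.23 higher (percentile 99.8). The G2/M list was at -0.80 (percentile 0), with 9 of 29 members at least 2-fold lower, the NF-kB list at -0.39 (percentile 0), the hypoxia list at -0.27 (percentile 0) and the ERK output list at -0.20 (percentile 0.22). The motility list was at -0.18 (percentile 0.09), the growth factor list at -0.18 (percentile 0) and the mesenchymal list at -0.08 (percentile 0.50). The integrin list (-0.08) and the TGF-beta response list (-0.05) lay just below the random range, the latter inside it under 3 of 10 alternatives. Of 14850 genes compared, 60 were at least 2-fold higher and 146 at least 2-fold lower. The share of lower genes was 70.9% and moved to 53.4% with scaling to the median and 85.4% in the authors' deposited values. Across 37 lists, 7 lay outside the central 95% of random lists for shDKK3 against shScr and 10 for shDKK3 against parental. For shScr against parental 11 did, where random lists would give 1.85. Members of a list can vary together and some lists share members, so 1.85 may be too low a yardstick.

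**Figure D3:**
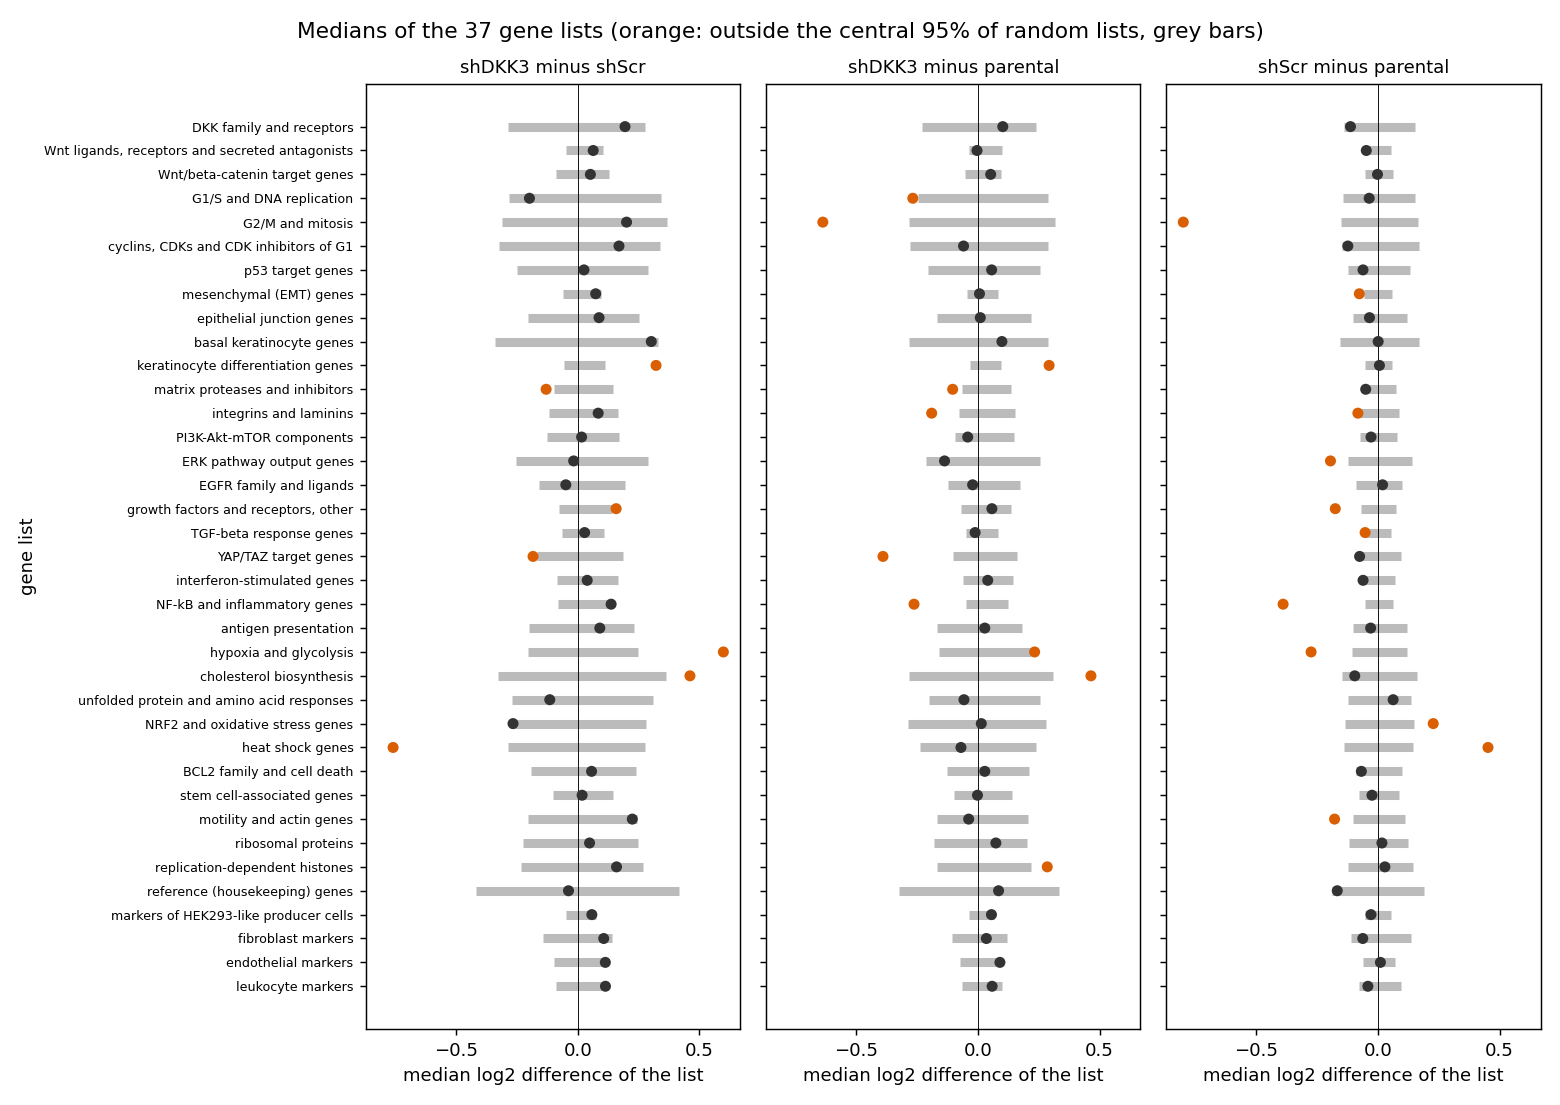
Median log2 difference of each of the 37 gene lists in the 3 comparisons (horizontal axes, log2), with grey bars for the central 95% of 10000 random lists matched on expression and orange points outside them. Differentiation and cholesterol genes lie above the bars against both controls, and heat shock genes lie below in the first panel (-0.76) and above in the third (0.45).

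Gene length went with the differences of the shDKK3 array. Genes at least 2-fold lower than both controls had a median genomic length of 38354 bp and those at least 2-fold higher one of 5987 bp. Across genes of the top tertile of expression, the rank correlation of length with the difference was -0.28 against shScr, -0.35 against parental and -0.00203 between the control arrays. The shortest of 10 length bins had medians of 0.44 and 0.38 against shScr and parental, and the ninth bin had the lowest medians, -0.29 and -0.33. The longest bin was at -0.18 and -0.26, so the trend did not continue to its end. SPRR1B (1698 bp), KRT16 (2990 bp) and SLPI (2326 bp), all higher on the shDKK3 array, are short, and ITGB1 (57913 bp) and GOLGA4 (123609 bp), both lower, are long. DKK1 (3377 bp) and CCND1 (13319 bp) were lower despite short genes. With the trend taken out, the hypoxia (0.70) and cholesterol (0.52) medians against shScr stayed above the random range, whereas the YAP/TAZ target median against shScr (-0.13) and the histone median against parental (0.08) lay inside it. The matrix protease median against shScr (-0.04), the G1/S median against parental (-0.18) and the TGF-beta median between the controls (-0.04) lay inside it as well. Against parental, the integrin (-0.09, from -0.19) and YAP/TAZ target (-0.21, from -0.39) medians shrank but stayed below the random range.

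**Figure D4:**
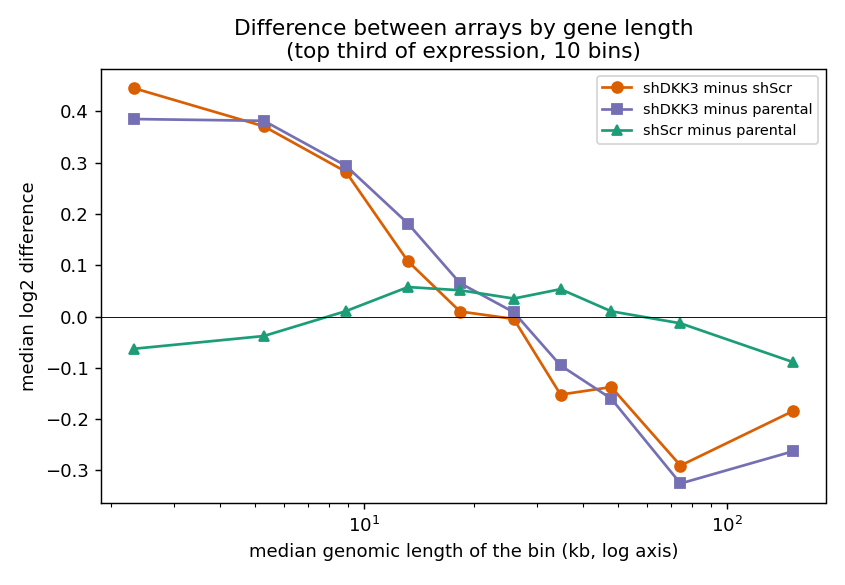
Median log2 difference (vertical) of genes in the top tertile of expression, in 10 bins of genomic length (horizontal, log axis in kb), for the 3 comparisons. Both shDKK3 lines run from above 0 for short genes to below 0 for long genes, and the line for shScr minus parental stays between -0.09 and 0.06.

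In the main setting, markers of other cell types gave no list outside the random range in either shDKK3 comparison, but some lay close to its edge. The 12 detected markers of HEK293-like cells, the kind used to make the virus, had a median of 0.06 against shScr (percentile 91.9) and of 0.06 against parental (percentile 94.5). Against parental they lay above the random range under 5 of 10 alternatives, with medians of 0.41 after subtraction of the blank mean, 0.35 with scaling to the 75th percentile and 0.13 with scaling to the median. The median of all genes was 0.10, 0.26 and 0.05 in these settings. After subtraction the fibroblast, endothelial and leukocyte markers were also above parental, at 0.17, 0.38 and 0.18, inside the random range. In the main setting, the fibroblast markers (0.11 and 0.03), the endothelial markers (0.11 and 0.09) and the leukocyte markers (0.11 and 0.06) were inside it. So were the reference genes (-0.04 and 0.09). Against shScr the endothelial and leukocyte markers lay at percentiles 97.4 and 97.3, and both were above the random range with no filter on dim probes (0.08 and 0.07). Without that filter, the HEK293-like markers against shScr (0.06) and the endothelial markers against parental (0.06) were above it too.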

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

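No test in this part was chosen after its result was seen. Probes without a gene name were outside the comparisons of the report, and some of them carried differences of the same size as named genes. On the shDKK3 array, 6 unnamed probes were at least 2-fold higher and 31 at least 2-fold lower than on each control array, out of 4223 unnamed probes. The shScr array stood apart from both other arrays in 11 unnamed probes, and the parental array in 1. What these probes measure was not analysed here.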

How the results depend on the processing

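In this part, the background column as local background and the removal of the length trend were chosen after the data were seen; no replicate could be left out, and no paired analysis was possible because each condition has 1 array. The counts depended on the treatment of dim signal and on the threshold, and are given as higher and lower for shDKK3 against shScr, shDKK3 against parental, shScr against parental and shDKK3 against both controls. Subtraction of the blank mean, which leaves folds of dim genes unshrunk, gave 1828 and 1885, 602 and 1663, 248 and 783, and 409 and 1169. An offset of 16 gave 701 and 1166, 248 and 783, 104 and 246, and 163 and 556. The authors' deposited values gave 2200 and 1604, 669 and 1622, 158 and 924, and 491 and 1089. A threshold of 1.5-fold gave 1445 and 1737, 1022 and 1403, 450 and 561, and 687 and 1024, and one of 3-fold gave 58 and 112, 13 and 37, 10 and 21, and 6 and 21. Scaling to the median gave 224 and 1262, 64 and 718, 95 higher in the control comparison, and 48 and 561. Scaling to the 75th percentile gave 200 higher against parental and 140 higher than both. For these scalings the cause was not tested. Other counts stayed within 1.5 times the reported one, except with the local background. Of the genes apart from both controls, 44 higher and 303 lower ones were kept with scaling to the median, 81 and 251 with the 75th percentile, 84 and 257 in the authors' values, 38 and 158 without the length trend, and 17 and 89 with the local background. Against shScr, the median of all genes moved to 0.36 with the 75th percentile, 0.32 in the authors' values and 0.23 after subtraction, from 0.03, and against parental to 0.26 with the 75th percentile and 0.11 in the authors' values. Between the controls it moved to -0.20 in the authors' values, -0.11 after subtraction and -0.10 with the 75th percentile.

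DKK3 stayed lower on the shDKK3 array under all alternatives chosen beforehand, and its difference to shScr was -0.80 with scaling to the median. Without the length trend, that difference was -0.23 and the one to parental -0.49. Of 28 list medians outside the random range, each alternative of the processing chosen beforehand kept at least 23 there, and of 7 against shScr, 5 stayed so with parental as the control and 6 with the mean of both controls. The matrix protease median changed sign with the 75th percentile (0.28 against shScr and 0.10 against parental) and in the authors' values (0.14 against shScr), all below the shift of all genes there. Of 162 named differences of at least 2-fold, 143 stayed so with scaling to the median, 150 with the 75th percentile, 149 in the authors' values and 140 without the length trend, and none changed sign under these.

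The local background column followed the brightness of its own spot (r from 0.891 to 0.935), and subtracting it moved many values, for which the cause was not tested. It gave 407 lower than shScr, 210 and 255 against parental, 205 higher in the control comparison and 162 lower than both, and DKK3 at 0.17 against shScr and 0.23 against parental. It kept 13 of the 28 list medians and 63 of the 162 named differences, and reversed 26. Against shScr these were EPCAM 0.99, WNT10A -0.10, PRIM1 0.13, AURKB -0.22, ACTA2 -0.23, FGFBP1 -1.24, F3 4.99, B2M 0.23, MVK -0.083, CHORDC1 0.16, BIRC2 0.78, BMI1 0.055, GUSB -0.026, GABARAPL1 0.42 and HSPA1B 0.071. Against parental they were ADAM9 0.11, FGFBP1 -0.17, F3 4.49, MVK -0.14, HSP90B1 0.10, CHORDC1 0.19, BIRC2 0.55 and PTX3 0.090, and between the controls GABARAPL1 -0.51, HSPA1B -0.062 and PTX3 0.10.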

Other observations

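In this part, the tests of scaling between arrays, of cross-hybridisation among keratins and of the shScr array's own difference were chosen after the result was seen.

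Against the parental array, which both comparisons share, 3 gene lists lay below the random range on both shRNA arrays. In 100 simulations of unchanged arrays with independent genes there was at most 1. Members of a list can vary together, which these simulations leave out, so they cannot say how unusual 3 lists are. Across genes the shRNA arrays showed no such likeness, at r = 0.015 against 0.497 in the simulation. The G2/M and mitosis list was at -0.64 on the shDKK3 array and -0.80 on the shScr array, the NF-kB list at -0.26 and -0.39, and the integrin and laminin list at -0.19 and -0.08. Others did not follow, with the hypoxia list at 0.23 and -0.27 and the YAP/TAZ target list at -0.39 and -0.08, the last inside the random range. Single mitotic genes did not follow the list on the shDKK3 array. AURKB, the chromosomal passenger kinase, was 0.83 above parental there and at -0.92 on the shScr array, and KIF2C, a mitotic kinesin, was at 0.45 and -0.83. SAA1 (-1.85 and -2.002) and PTX3 (-1.75 and -1.89), acute-phase genes, were lower on both shRNA arrays, whereas VIM (-0.78 and -4.32) and LGALS1 (0.99 and -2.37) were 2-fold lower on the shScr array alone.

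The shDKK3 array stood apart from both controls in 390 genes, for which noise of single spots is argued against, since the differences to shScr of 2 probes of a gene correlated at r = 0.775 over 1624 genes. Scaling is argued against as the source of the excess of lower genes, whose lowest share among these genes over the scalings was 64.7%. Against shScr alone that excess stays open, with 42.2% lower in the authors' values and 50.8% after subtraction of the blank mean. A trend with gene length cannot be told apart from the pattern as a cause of part of it, since 50.3% of the genes (196) stayed apart once the trend was taken out, between the bounds set for that test. Such a trend may come from RNA quality or amplification on 1 array or from the cells, and a difference set by the DKK3 shRNA stays untested with 1 array per condition.

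The keratinocyte differentiation list was higher on the shDKK3 array, and the basal list lay inside the random range against both controls but above it against shScr under 6 of 10 alternatives (0.70 after subtraction of the blank mean). The test of cross-hybridisation among keratin paralogs bears only on whether the median of the differentiation list rests on its keratins. Without its keratins and KRTDAP, not itself a keratin, the remaining 32 members had a median 0.28 above shScr, where random lists reach 0.11. Few members of that list are keratins, so leaving them out could hardly move its median. The test therefore cannot say whether the keratin signals are cross-hybridised, and cross-hybridisation among the other members was not tested. The keratins of the basal list were not tested in this way, and cross-hybridisation stays open for them. Gene length remains open in part for the differentiation list. Its median against shScr was 0.32 before and 0.20 after the trend was taken out, which is 63.3% of its size. Whether the DKK3 shRNA changed these genes stays untested with 1 array per condition.

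Heat shock genes were lower on the shDKK3 array than on the shScr array. A candidate explanation is that the shScr array itself differs, since its heat shock median was 0.45 above parental and the shDKK3 median was at -0.07 against parental, inside the random range. This goes with a difference of the shScr cells or of that array, which cannot be separated further here. HSPD1 (-1.08), CHORDC1 (-1.02) and DNAJA1 (-1.30) were nonetheless also 2-fold lower on the shDKK3 array than on the parental array, although HSPD1 was 1.74-fold lower in the authors' values.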
